A study of Homo sapiens with 6 samples.

How the data were processed

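Total RNA of 6 samples, 3 labelled HCC827 and 3 labelled HCC827_Er, was sequenced after library preparation with an Illumina TruSeq RNA kit, per the labels' protocols. The authors deposited 1 table of FPKM values per gene and library, with Ensembl gene identifiers and no counts. Reads were processed with fastp, HISAT2 and StringTie, per the submitters' processing notes, which name GRCh38.p14 and hg19 as builds without their roles. Tool versions, the gene annotation and the rule by which genes entered the table are not given in the sources used here. FPKM is scaled by transcript length and by the mapped fragments of the library, so a few very abundant transcripts lower the values of all others, and the table shows neither depth nor counting error. The listed genes summed to between 184633 and 224211 FPKM per library, a part of each library and not its depth. The 10 most abundant genes held between 21.4% and 26.3% of these sums. Between 286 and 382 genes were listed at 0 in a library, while genes used by every cell, such as PGK1 with a lowest value of 387 FPKM, were not. No 2 libraries of one line had more than 317 of the 6641 genes at identical values. Among genes with FPKM of at least 10 it was no more than 4, so no library was counted as a copy of another of its line.

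Gene symbols were matched by identifier for 6636 of the 6641 genes. Gene types, positions, transcript lengths and GC content were taken by identifier from GENCODE 29 on GRCh38, which listed 6353 of the genes and gave 5241 of them as protein-coding. It need not be the annotation the authors used, and the table itself holds no coordinates.

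FPKM values were transformed to log2(FPKM + 1) as deposited, with no further rescaling. Differences are on this scale, which understates the change of low genes. Genes with FPKM of at least 1 in 3 or more of the 6 libraries were tested, which left 5276 genes and set 1365 aside. A linear model with the cell line as its only term was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend), and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called at an adjusted p under 0.05 and an absolute log2 difference of at least 1, a 2-fold change. An exact test of 3 against 3 libraries cannot give a two-sided p below 0.10, so single genes were tested in the model alone. Means and SDs are of FPKM over the 3 libraries of a line. The steps were tested on simulated data for HCC827_Er against HCC827, with 200 changed genes among 4993 tested. The test called 97% of 100 genes changed by 1.5 on the log2 scale, 100% of 100 genes changed by 3, and 0.0417% of the unchanged genes. The changed genes were drawn only from those with a mean log2(FPKM + 1) above 2, so the rates do not cover lower genes. Most simulated genes were unchanged, unlike those of the deposited table, so the rates check the steps and do not describe these data.

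The test, its threshold, 28 gene lists and the rule for named genes were fixed before the data were examined. Lists with at least 5 tested genes, 20 of the 28, were compared with the other tested genes by limma's camera. It was run with a preset correlation of 0.01, adjusted over the 20 lists, and again with the correlation estimated from the data. With an estimated correlation camera also tests on the 4 residual degrees of freedom of the fit, which weakens the test. The other 8 lists were described by their members. Named genes were the 12 called genes with the largest positive and the 12 with the largest negative log2 difference. They had to have a symbol, no overlap between the lines and a mean FPKM of at least 5 in the higher line, with antisense, pseudogene and unnamed loci left out. To these were added 10 fixed names (EGFR, MET, AXL, ERBB2, ERBB3, BEX2, EP300, CDH1, VIM and ZEB1), and from each list up to 4 called members with the largest differences, or 2 tested members where none was called. Beyond this rule NKX2-1, NAPSA, ABCA3, SCGB3A2, FN1, KRT8, ABCB1, CD68, TRIM29, CCL20, LUM, KAT2B, ACADS and H4C8 were named after their values were seen, as were all genes named under the other observations alone. Some genes that the rule names are not reported here. Of the fixed names EGFR, ERBB2, BEX2 and EP300 were not in the table used here.

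The alternatives were pseudocounts of 0.1 and 5, other minima of FPKM, median-ratio, sum and quantile rescaling, limma without the trend or with robust estimation, no minimum difference, a test against a log2 difference of 1, rows of one symbol summed, the replicate number as a block, and each library left out in turn. In rescaled fits and fits with a library left out the minimum FPKM was first applied to the values entering the fit; keeping it on the deposited values was decided after those results had been seen. The planned sum rescaling also raised all values against the pseudocount, so rescaling to the geometric mean of the 6 library sums was added after its results had been seen, and is the sum rescaling of the report. Chromosome positions, gene families, and length and GC content were examined with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The closing section gives the effect of these settings.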

Results

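RNA sequencing was carried out on 2 human cell lines with 3 libraries each. HCC827 is an established lung adenocarcinoma line that carries an activating mutation of EGFR, the receptor of epidermal growth factor. The other line is labelled HCC827_Er, and the series title speaks of parental and resistant cells. The deposited values were FPKM, fragment numbers scaled by transcript length and by the mapped fragments of the library, so the sequencing depth of the libraries was unknown. The table listed 6641 genes, and their FPKM summed to between 184633 and 224211 per library. Libraries of one line correlated across the listed genes with r between 0.991 and 0.994, and libraries of different lines with r between 0.806 and 0.809; genes are not independent replicates. Whether the 3 libraries of a line came from separate cultures is not stated, so the p-values measure only the spread between these samples.

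The listed genes were not a sample of the transcriptome. Of 2356 genes with a mean FPKM of at least 10, only 16 had a ratio within 0.4 of equal on the log2 scale. The libraries of the lines did not overlap for 96.1% of the listed genes, where chance gives 10%. Almost all genes in the table thus differed between the lines before any test was made. Counts of called genes, adjusted p-values and the comparison of a gene list with the other genes hold only within this list, which is no independent evidence that its genes differ.

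**Figure D1:**
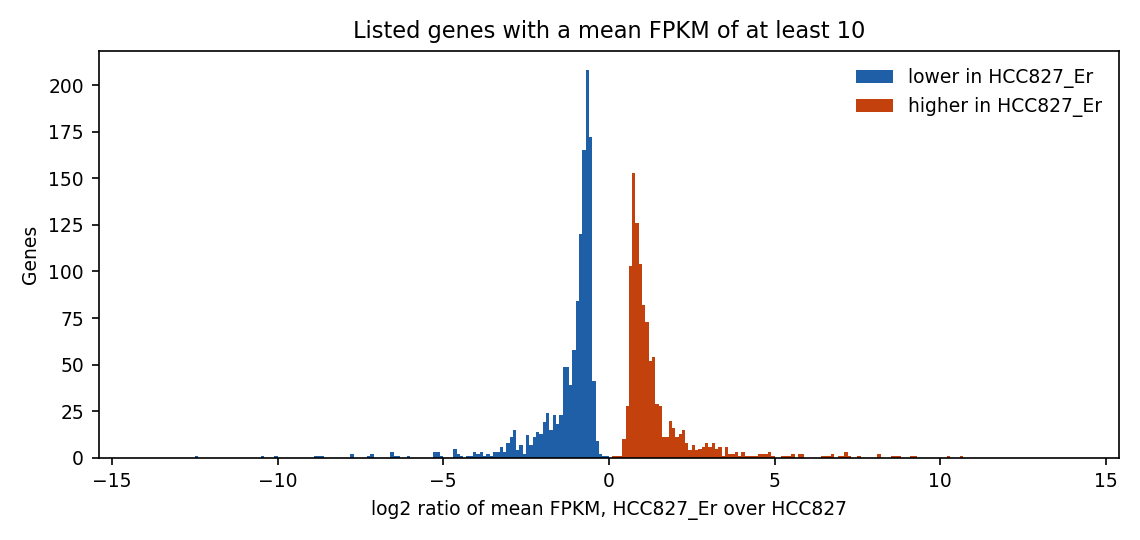
Histogram of the log2 ratio of mean FPKM, HCC827_Er over HCC827, for listed genes with a mean FPKM of at least 10 that were above 0 in both lines (x axis, log2 ratio; y axis, number of genes). Only 16 of the 2356 genes with a mean of at least 10 lay within 0.4 of a log2 ratio of 0, which leaves a gap between the genes lower (blue) and higher (orange) in HCC827_Er.

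The series addresses how histone crotonylation, a modification of lysine residues, relates to resistance to EGFR inhibitors, through the transcripts that differ between HCC827_Er and HCC827. S100A9 and S100A8, which encode the subunits of the calcium-binding protein calprotectin, were among the genes with the largest rise in HCC827_Er. S100A9 (ENSG00000163220) stood at 8.84 ± 1.21 FPKM in HCC827 and 1225 ± 74.5 FPKM in HCC827_Er (SD, n = 3), a difference of 6.97 on the log2(FPKM + 1) scale (SE 0.090, limma adjusted p = 2.27e-10). S100A8 rose from 0.277 ± 0.479 to 115 ± 14.2 FPKM, and AGR2, a secretory pathway protein of mucous epithelia, from 0.177 ± 0.204 to 107 ± 9.0 FPKM. ALDH1A1, a retinaldehyde dehydrogenase, showed the largest fall. ALDH1A1 (ENSG00000165092) stood at 883 ± 27.7 FPKM in HCC827 and 0.840 ± 0.462 FPKM in HCC827_Er (log2 difference -8.94, SE 0.15, adjusted p = 7.93e-10). SPP1, which encodes osteopontin, fell from 4145 ± 119 to 44.2 ± 2.40 FPKM, and the tight junction gene CLDN2 from 187 ± 3.74 to 0.887 ± 0.237 FPKM.

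Of 5276 genes tested, 1304 were called higher and 1041 lower in HCC827_Er, at an adjusted p under 0.05 and a difference of at least 2-fold. Of these, 379 were higher and 288 were lower by 4-fold or more. All but 89 of the tested genes had an adjusted p under 0.05, so passing that threshold alone did not set a gene or list apart. The other genes with the largest rises were SFTA2, PRODH, ADGRF1, MUC5B, DEFB4A, S100A7, CYP24A1, SFTPB and CEACAM6. The other genes with the largest falls were GSTA1, AKR1C2, VCAM1, IL13RA2, LBP, PTPRD, GSTA2, IGFBP7 and NR1H4. GSTA1, VCAM1, IL13RA2 and GSTA2 were listed at 0 in all 3 HCC827_Er libraries, so no fold is given for them. DEFB4A, AKR1C2, GSTA1 and GSTA2 have near-identical copies in the genome, and the split of their reads is uncertain. With median-ratio rescaling of the libraries the split was 896 higher and 1657 lower, and with rescaling of each library to the mean sum of the 6 it was 1825 higher and 794 lower. These rescalings moved HCC827_Er against HCC827 by -0.34 and 0.25 on the log2 scale, so the balance of higher and lower genes was not fixed by the table. Where the called members of a list differed from those as deposited, their numbers with the first and then the second rescaling are given in brackets below.

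Epithelial genes rose in HCC827_Er, with 23 of 26 tested members called higher and none lower (rescaled, 21 higher and 1 lower, then 24 and 0). ESRP1, a splicing regulator of epithelial cells, rose from 3.27 ± 0.233 to 87.6 ± 3.83 FPKM, and the adhesion molecule EPCAM from 30.1 ± 0.429 to 297 ± 26.4 FPKM. The transcription factor GRHL2 rose from 0.210 ± 0.0436 to 14.2 ± 1.89 FPKM, the trafficking GTPase RAB25 from 0.0933 ± 0.0862 to 10.3 ± 1.22 FPKM, and CDH1, which encodes E-cadherin, from 60.7 ± 1.63 to 161 ± 2.07 FPKM. KRT8 was the only member with a negative log2 difference (-0.77), at 1744 FPKM in HCC827 and 1025 FPKM in HCC827_Er, and was called lower with median-ratio rescaling alone of these 3 scalings. The list stood above the other tested genes (camera adjusted p = 1.32e-06), and its adjusted p = 0.150 with an estimated correlation between genes.

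Mesenchymal genes moved both ways, with 6 of 16 called higher and 7 called lower (rescaled, 6 and 8, then 7 and 6), and the list did not stand apart (camera adjusted p = 0.827). VIM, the intermediate filament of mesenchymal cells, fell from 398 ± 23.2 to 76.2 ± 3.62 FPKM. The repressor of E-cadherin ZEB1 fell from 8.27 ± 0.0764 to 1.42 ± 0.177 FPKM, and the N-cadherin gene CDH2 from 7.96 ± 0.173 to 0.117 ± 0.0833 FPKM. In the other direction, the matrix genes SPARC and COL1A1 rose from 0.250 ± 0.118 to 17.8 ± 2.05 FPKM and from 0.750 ± 0.243 to 10.1 ± 0.932 FPKM, and FN1, which encodes fibronectin, rose from 75.0 to 449 FPKM. Output genes of YAP and TGF-beta fell, with 11 of 15 called lower and 1 called higher (rescaled, 11 and 0, then 9 and 1; camera adjusted p = 0.00159; adjusted p = 0.150 with an estimated correlation). ANKRD1 fell from 45.3 ± 3.34 to 1.85 ± 0.440 FPKM and CCN2 from 34.9 ± 1.42 to 1.46 ± 0.401 FPKM, while AXL belongs to this list as well.

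**Figure D2:**
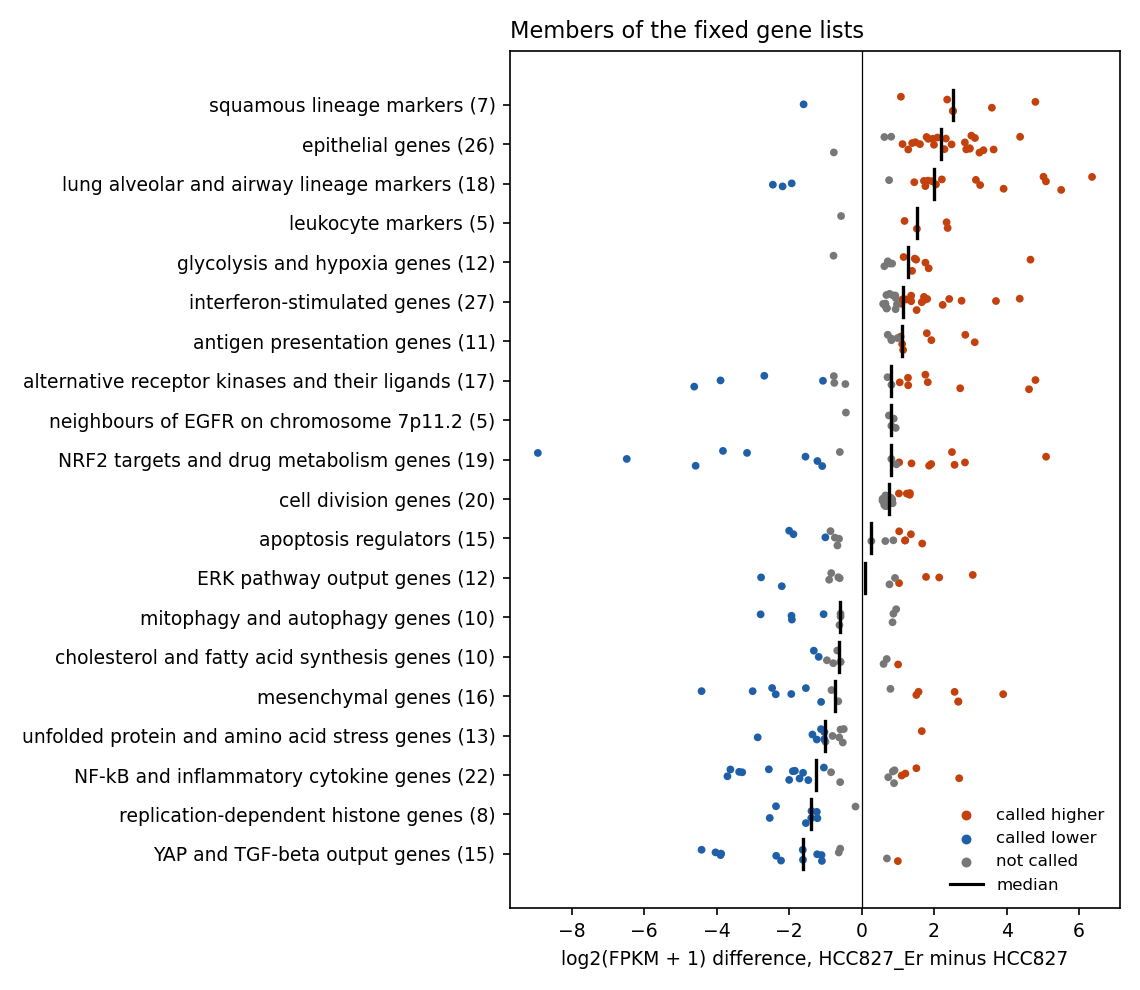
Log2(FPKM + 1) difference, HCC827_Er minus HCC827, of each tested member of the 20 gene lists with at least 5 tested genes (x axis; 1 row per list, with its number of tested genes in brackets). Points are genes, called higher (orange), called lower (blue) or not called (grey), spread vertically for legibility, and black bars are list medians; 23 of the 26 epithelial genes were called higher and 11 of the 15 YAP and TGF-beta output genes lower.

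Lung lineage markers rose in HCC827_Er, with 14 of 18 called higher and 3 called lower (camera adjusted p = 0.00443; adjusted p = 0.150 with an estimated correlation). The list did not pass the test without any 1 HCC827_Er library when the minimum FPKM was applied to the other 5 (adjusted p of 0.0983 to 0.122). SFTA2, a surfactant-associated gene, rose from 3.53 ± 2.04 to 350 ± 38.3 FPKM, and SFTPB, surfactant protein B of alveolar type II cells, from 0.213 ± 0.327 to 39.6 ± 4.88 FPKM. The airway mucin gene MUC5B rose from 0.130 ± 0.0173 to 50.7 ± 6.59 FPKM and the adhesion molecule CEACAM6 from 0.0200 ± 0.0200 to 32.1 ± 0.935 FPKM. NKX2-1, the transcription factor of lung epithelium, rose from 5.93 to 65.7 FPKM, and NAPSA, an aspartic protease of alveolar cells, from 28.0 to 257 FPKM. The members called lower included ABCA3 and SCGB3A2. Squamous lineage markers also rose, with 6 of 7 called higher and TRIM29 called lower (rescaled, 5 and 1, then 6 and 1; camera adjusted p = 0.0310; adjusted p = 0.166 with an estimated correlation), and were too few to test in those same fits. They included KRT16, at 0.237 ± 0.224 against 33.0 ± 0.940 FPKM, the transcription factor SOX2, at 0.180 ± 0.0600 against 13.3 ± 1.48 FPKM, KRT15, at 7.69 ± 0.419 against 49.1 ± 3.33 FPKM, and TP63, the regulator of basal and squamous cells, at 0.170 ± 0.0819 against 5.71 ± 0.746 FPKM. Of the neuroendocrine markers only POU2F3, a transcription factor of tuft cells, was tested, and it rose from 0.220 ± 0.115 to 1.58 ± 0.506 FPKM (not called with median-ratio rescaling).

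Alternative receptor kinases and their ligands moved both ways, with 8 of 17 called higher and 4 called lower (rescaled, 6 and 6, then 8 and 3; camera adjusted p = 0.457). MET, a receptor whose amplification is a known route of resistance to EGFR inhibitors, stood at 99.4 ± 4.62 FPKM in HCC827 and 164 ± 9.41 FPKM in HCC827_Er. Its log2 difference of 0.72 (SE 0.061, adjusted p = 5.61e-06) lay under the 2-fold minimum. AXL, a receptor kinase of the TAM family, fell from 32.5 ± 1.21 to 1.26 ± 0.200 FPKM (log2 difference -3.89, SE 0.10, adjusted p = 5.80e-09), and FGFR1 fell from 73.9 ± 5.09 to 2.08 ± 0.592 FPKM. The binding proteins of insulin-like growth factors IGFBP3 and IGFBP2 rose from 39.0 ± 1.97 to 984 ± 33.8 FPKM and from 0.220 ± 0.121 to 32.9 ± 2.14 FPKM. Of the neighbours of MET on chromosome 7, CAV2 fell from 189 ± 13.0 to 52.6 ± 4.77 FPKM, and the other tested neighbour was called lower with median-ratio rescaling alone.

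Of the EGFR family and its ligands, 3 genes were tested. EGF rose from 0.587 ± 0.341 to 2.62 ± 0.994 FPKM (not called with median-ratio rescaling), HBEGF fell from 7.33 ± 0.317 to 1.85 ± 0.405 FPKM, and ERBB3 stood at 22.7 ± 1.99 and 38.2 ± 2.30 FPKM, under the 2-fold minimum. EGFR, ERBB2, BEX2 and EP300 were not analysed here. None of the 5 tested neighbours of EGFR on chromosome 7 was called as deposited or with median-ratio rescaling, and 4 were called higher with the mean sum (medians 0.82, 0.48 and 1.07; camera adjusted p = 0.281 as deposited). Like all but 89 of the 5276 tested genes, all 5 had an adjusted p under 0.05 as deposited. Among them SEC61G, a subunit of the protein translocation channel, stood at 5002 ± 318 and 9698 ± 1676 FPKM, and ZNF713 at 2.60 ± 0.784 and 5.65 ± 1.39 FPKM. Of the output genes of the ERK pathway, 4 of 12 were called higher and 2 lower (rescaled, 3 and 4, then 6 and 2; camera adjusted p = 0.952), and the median (0.083) and mean (0.15) of the list differed in sign from its test. DUSP6, a phosphatase that acts on ERK, rose from 6.43 ± 1.09 to 61.0 ± 1.78 FPKM and the potassium channel gene KCNN4 from 2.60 ± 0.582 to 14.8 ± 1.17 FPKM, while the immediate early genes FOS and EGR1 fell from 204 ± 14.2 to 29.1 ± 3.65 FPKM and from 76.1 ± 4.88 to 15.7 ± 0.248 FPKM.

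**Figure D3:**
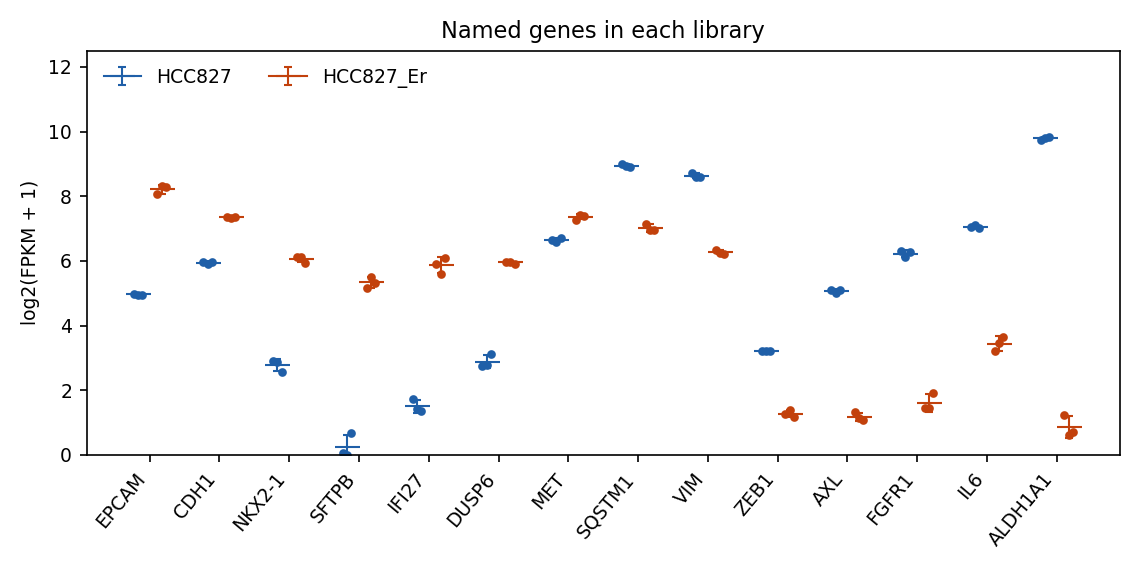
Expression of 14 named genes as log2(FPKM + 1) (y axis) in the 3 HCC827 libraries (blue) and the 3 HCC827_Er libraries (orange). Points are libraries, horizontal bars are means and error bars are SDs (n = 3); the libraries of the lines did not overlap for any gene shown, including MET, which lay under the 2-fold minimum.

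Of the writers, erasers and readers of histone crotonylation, 3 of 26 listed names were in the table and none was called, as deposited or with either rescaling. TAF1 stood at 15.4 ± 3.91 FPKM in HCC827 and 25.5 ± 1.17 FPKM in HCC827_Er, and DPF2, a reader of acylated histone H3, at 35.1 ± 0.569 and 22.2 ± 1.87 FPKM. KAT2B, an acetyltransferase, stood at 3.46 and 2.24 FPKM. Of the genes of crotonyl-CoA and short-chain acyl-CoA metabolism, HADH, ACADS and ACLY were tested and none was called as deposited, while ACLY was called lower with median-ratio rescaling and HADH higher with the mean sum. HADH stood at 25.2 ± 1.65 and 43.5 ± 2.14 FPKM, and ACLY, which makes cytosolic acetyl-CoA, at 221 ± 10.4 and 132 ± 2.40 FPKM. Like all but 89 of the 5276 tested genes, all 6 had an adjusted p under 0.05 as deposited, and the 6 differed by less than 2-fold. Replication-dependent histone genes fell, with 7 of 8 called lower (rescaled, 7, then 5; camera adjusted p = 0.00689; adjusted p = 0.150 with an estimated correlation). Among them H2BC5 fell from 36.1 ± 1.64 to 5.46 ± 1.08 FPKM, H2AC6 from 167 ± 25.9 to 31.3 ± 0.278 FPKM, H1-2 from 41.5 ± 7.17 to 13.6 ± 1.78 FPKM and H2BC21 from 11.21 ± 0.421 to 3.66 ± 0.106 FPKM. H4C8 stood at 7.68 and 6.84 FPKM, within the spread of its libraries, and reads of such histone genes can be shared between near-identical copies.

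Interferon-stimulated genes rose in HCC827_Er, with 15 of 27 called higher and none lower (rescaled, 13, then 20 higher), and all 27 had a positive difference at an adjusted p under 0.05 (camera adjusted p = 2.11e-05; adjusted p = 0.150 with an estimated correlation). Of all 5276 tested genes, 2672 were higher at that adjusted p and 1304 were called higher. IFI27 rose from 1.84 ± 0.386 to 57.8 ± 9.59 FPKM, BST2, which tethers enveloped viruses, from 10.7 ± 0.872 to 151 ± 2.80 FPKM, XAF1 from 1.63 ± 0.377 to 16.8 ± 2.13 FPKM and DDX60 from 3.44 ± 0.366 to 22.7 ± 1.88 FPKM. Antigen presentation genes rose as well, with 7 of 11 called higher and none lower (rescaled, 4, then 10 higher; camera adjusted p = 0.00452; adjusted p = 0.150 with an estimated correlation). HLA-DRB1 rose from 1.78 ± 0.206 to 23.2 ± 1.36 FPKM, HLA-DRA from 1.14 ± 0.544 to 6.92 ± 0.185 FPKM, and CD274, which encodes the ligand PD-L1, from 5.06 ± 1.80 to 19.5 ± 2.89 FPKM. HLA-DRB5 rose from 0.183 ± 0.0569 to 7.78 ± 2.12 FPKM, and reads of the HLA-DRB genes can be shared. Of the leukocyte markers, 4 of 5 were called higher (camera adjusted p = 0.239): CSF1R reached 5.45 ± 1.71 FPKM in HCC827_Er, CORO1A 7.66 ± 0.966, LAPTM5 4.49 ± 0.370 and CD14 1.73 ± 0.176. CD68 stood at 174 FPKM in HCC827 and 117 FPKM in HCC827_Er and was not called.

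Targets of NF-kB and inflammatory cytokines included 12 genes called lower and 4 called higher of 22 (rescaled, 13 and 2, then 11 and 6), and the list did not pass the test (camera adjusted p = 0.0799; 0.0230 to 0.0338 without any 1 HCC827 library and the minimum on the other 5). IL6 fell from 132 ± 4.26 to 9.92 ± 1.73 FPKM, and the chemokine genes CXCL5 and CCL2 from 2458 ± 118 to 236 ± 27.1 FPKM and from 63.0 ± 4.08 to 4.04 ± 1.46 FPKM. IL32 fell from 39.2 ± 2.17 to 3.14 ± 0.846 FPKM, while the chemokine gene CCL20 rose from 34.1 to 227 FPKM. Fibroblast and endothelial markers were too few to test as lists: COL1A1 rose as above, LUM stood at 1.81 and 0.530 FPKM (log2 difference -0.87, called with median-ratio rescaling alone of the 3 scalings), and EGFL7 stood at 9.07 ± 0.551 and 6.61 ± 0.386 FPKM.

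Genes of glycolysis and the hypoxia response rose, with 7 of 12 called higher and none lower (rescaled, 6 and 1, then 9 and 0; camera adjusted p = 0.00689; adjusted p = 0.150 with an estimated correlation). EGLN3, a prolyl hydroxylase that acts on hypoxia-inducible factors, rose from 1.59 ± 0.491 to 63.8 ± 5.04 FPKM, and VEGFA from 93.7 ± 4.30 to 320.0 ± 7.39 FPKM. The hexokinase gene HK2 rose from 5.43 ± 0.221 to 22.2 ± 0.0557 FPKM and the glucose transporter gene SLC2A3 from 0.447 ± 0.300 to 3.05 ± 0.184 FPKM. NRF2 targets and drug metabolism genes moved both ways, with 8 of 19 called higher and 8 lower (rescaled, 7 and 8, then 10 and 6; camera adjusted p = 0.952). Their median log2 difference was 0.82 and their mean -0.55, with the test in the direction of the mean. CYP24A1, which inactivates vitamin D, rose from 1.54 ± 0.192 to 85.6 ± 4.05 FPKM. The aldo-keto reductase gene AKR1C2 fell from 228 ± 10.4 to 1.56 ± 0.151 FPKM, the glucuronosyltransferase gene UGT1A6 from 30.8 ± 0.618 to 0.330 ± 0.105 FPKM, and the drug efflux pump gene ABCB1 from 17.2 to 0.290 FPKM. UGT1A6 shares most of its exons with other genes of its locus, so its reads are uncertain. Of the genes of cholesterol and fatty acid synthesis, HMGCS1 and SQLE were called lower and SREBF1 higher of 10 (rescaled, 5 lower and 0 higher, then 1 and 1; camera adjusted p = 0.281). HMGCS1 fell from 51.6 ± 5.70 to 22.1 ± 2.48 FPKM, SQLE from 18.4 ± 0.660 to 6.83 ± 1.01 FPKM, and SREBF1 rose from 40.3 ± 3.78 to 82.3 ± 9.50 FPKM. MT-RNR1, the mitochondrial 12S ribosomal RNA and the one mitochondrial gene in the table, fell from 15219 ± 176 to 6482 ± 22.4 FPKM (not called with the mean sum).

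Genes of the unfolded protein and amino acid stress responses fell, with 6 of 13 called lower and 1 higher (rescaled, 8 and 1, then 2 and 1; camera adjusted p = 0.00583; adjusted p = 0.166 with an estimated correlation). The stress transcription factors ATF3 and DDIT3 fell from 64.3 ± 8.17 to 8.04 ± 2.09 FPKM and from 40.5 ± 2.62 to 16.6 ± 0.886 FPKM, and HERPUD1 from 104 ± 5.92 to 39.9 ± 4.69 FPKM, while DDIT4, an inhibitor of mTORC1, rose from 168 ± 10.2 to 533 ± 34.7 FPKM. Of the mitophagy and autophagy genes 4 of 10 were called lower and none higher (rescaled, 4 and 0, then 3 and 2), and the list did not pass the test (camera adjusted p = 0.106). GABARAPL1 fell from 162 ± 2.15 to 22.6 ± 0.802 FPKM, MAP1LC3B from 121 ± 5.59 to 30.9 ± 2.32 FPKM, the autophagy receptor gene SQSTM1 from 493 ± 15.6 to 129 ± 10.7 FPKM and OPTN from 17.1 ± 0.210 to 7.83 ± 1.40 FPKM. Cell division genes rose by less, with 4 of 20 called higher (rescaled, 0, then 10, with medians of 0.43 and 1.00), and all 20 had a positive difference at an adjusted p under 0.05 (camera adjusted p = 0.000148; adjusted p = 0.166 with an estimated correlation). Over all 5276 tested genes, 2672 were higher at that adjusted p and 1304 were called higher, so the 4 called members were no excess. MCM6 rose from 19.2 ± 1.38 to 49.8 ± 2.17 FPKM, RRM2 from 41.0 ± 3.18 to 105 ± 7.99 FPKM, PCNA from 98.5 ± 2.56 to 235 ± 4.22 FPKM and TOP2A from 90.3 ± 3.64 to 186 ± 15.1 FPKM. Apoptosis regulators moved both ways, with 5 of 15 called higher and 3 lower (rescaled, 2 and 5, then 6 and 2; camera adjusted p = 0.952), and the median (0.27) and mean (0.034) of the list differed in sign from its test. BMF rose from 13.1 ± 2.16 to 43.5 ± 1.11 FPKM and BCL2L2 from 11.9 ± 0.635 to 32.2 ± 0.992 FPKM. BIRC3 fell from 218 ± 11.5 to 54.0 ± 5.47 FPKM and BCL2 from 2.79 ± 0.180 to 0.0267 ± 0.0153 FPKM.

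In all 28 lists the numbers of members called were equal when adjusted over the list alone and over all genes tested. The calls of all 10 lists past the threshold were lost with an estimated correlation, a setting that also left the test only 4 degrees of freedom. The estimates for the glycolysis and replication-dependent histone lists were -0.028 and -0.041, below the preset 0.01. A larger correlation thus does not account for the loss of those calls. The directions given here rest on the names of the deposited columns.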

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

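The alternatives that used protein-coding genes alone, centred the gap in the log2 ratios on 0, rescaled to the mean sum of the libraries, or kept the minimum FPKM on the deposited values of all 6 libraries in fits with a library left out or rescaled were chosen after seeing the data. No gene called in the main setting was called in the other direction under any alternative. Median-ratio and sum rescaling moved the lines by -0.34 and 0.25 on the log2 scale, less than the minimum difference of 1. They could thus not have reversed a call. The 1304 higher and 1041 lower genes became 579 and 506 with a pseudocount of 5, 749 and 637 with a mean FPKM of at least 5 (fewer genes tested), 2672 and 2515 with no minimum difference, and 827 and 664 with a test against a log2 difference of 1. With the minimum so kept, median-ratio rescaling gave 896 and 1657, and rescaling to the mean sum 1825 and 794. One fixed sum per library gave 2214 and 992, but it also multiplied all values by 4.46 to 5.42, so that the pseudocount stood for 0.185 to 0.224 FPKM. Since the table holds part of each library, no rescaling has a known set of unchanged genes. The other settings over all 6 libraries stayed within 1.5 times, with 1116 to 1705 higher and 816 to 1298 lower. Leaving out 1 library gave, with the minimum so kept, 1298 to 1334 higher, 1034 to 1056 lower and 10 lists past the threshold each time. In the planned fits as first run, with the minimum on the remaining 5 libraries, the counts were 877 to 1334 higher, 759 to 1056 lower and 8 to 11 lists, since genes on in only the shortened line were no longer tested. The lung lineage list then had an adjusted p of 0.0983 to 0.122 without any 1 HCC827_Er library, where the squamous and leukocyte lists kept under 5 genes and could not be tested, and the NF-kB list one of 0.0230 to 0.0338 without any 1 HCC827 library. With the minimum after rescaling, also planned and as first run, they were 884 and 1670 (median ratio) and 2742 and 1264 (fixed sum, where the minimum was lowered as the pseudocount was, 6297 genes tested). With an estimated correlation 0 of the 10 lists passed, at adjusted p of 0.150 to 0.166; the other list alternatives over all 6 libraries left 10.

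The replicate block gave 1304 higher, 1041 lower and 10 lists, and changed no call of a gene. Deviations of libraries with the same number correlated across genes at 0.106, -0.0219 and 0.0489, and those with different numbers at -0.0901 to 0.0410. HCC827 replicates 1 and 3 correlated best with their own number and replicate 2 did not. These values show no clear pairing by number, and pairing was not tested.

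Lists far from the threshold turned direction without passing it, and the cause was not tested. These were the NRF2 list (adjusted p 0.985 with a pseudocount of 0.1, 0.966 with median-ratio rescaling, 0.946 with the minimum after it, and 0.859, 0.898 and 0.879 without HCC827 replicate 1, 2 and 3 and the minimum on the rest) and the apoptosis list (0.988 with the replicate block, 0.964 without HCC827 replicate 1, where leaving out any library gave 0.937 to 0.987, and, with the minimum on the rest, 0.905 without HCC827 replicate 1 and 0.881, 0.828 and 0.876 without HCC827_Er replicate 1, 2 and 3). The ERK list (0.983 with the minimum after median-ratio rescaling, 0.922, 0.912 and 0.965 without HCC827_Er replicate 1, 2 and 3 and the minimum on the rest) and the mesenchymal list (0.989 without HCC827 replicate 3 and the minimum on the rest) did so too. The medians of the ERK and apoptosis lists were -0.21 and -0.033 with median-ratio rescaling. H4C8, never called, stood at -0.17 in the main setting and turned to 0.050 with the mean sum, 0.053 with the fixed sum, under either minimum, and to 0.00048 without HCC827_Er replicate 3, in a range from -0.37 without HCC827_Er replicate 2. Of 3601 values of named genes under the alternatives, 3487 kept direction and call, 67 lost the call, 42 gained it and these 5 of H4C8 turned direction. Depth is unknown, so counting error could not be separated from other spread.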

Other observations

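The tests chosen only after the result was seen were those of shared reads, of transcript length and GC content, of the spread within the chromosome 17 segment, of labels, of other splits of the libraries and of the ZNF genes by called genes and by camera; the tests on 20 Mb bins and on the share of genes listed for chromosomes 14 and X were set down before. A first correction for length and GC by regression had left the median of the segment's lower protein-coding genes at -2.60 and both chromosomes at 86.7%, and was then replaced by the comparison with matched genes. For the segment this comparison and the test of shared reads were first run on its 15 lower protein-coding genes, and then on all 22 tested genes.

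Along the genome, 2 stretches of neighbouring tested genes moved together beyond what shuffled gene positions gave. The mean log2 difference over 10 neighbouring genes departed from the mean of all genes on these chromosomes by up to 3.01, in either direction. The bound on this departure from 10000 permutations was 2.13. The stretch on chromosome 1 from 152514502 to 153631360 (GENCODE 29, GRCh38) holds genes of the cornified envelope and S100 calcium-binding proteins, and 15 of its 17 tested genes were higher in HCC827_Er (median log2 difference 1.72, or 1.57 with median-ratio rescaling and 1.80 with rescaling to the mean sum of the libraries). It includes S100A7, S100A8, S100A9, SPRR1B and IVL. Of 52 families of gene symbols with at least 8 tested members, only the ZNF genes, mostly zinc finger transcription factors, passed a Fisher's exact test of direction, which treats genes as independent. At an adjusted p under 0.05, 74 of the 111 tested ZNF genes were higher and 33 lower (two-sided Fisher's exact test against the other tested genes, p = 0.000262, adjusted p = 0.0136). By the 2-fold call only 18 were higher and 10 lower (Fisher's exact test, p = 0.445), and camera gave p = 0.0652 with the preset correlation and p = 0.210 with an estimated one, so the ZNF genes did not stand apart by these 3 tests. Their median log2 difference of 0.55 was 0.29 with median-ratio rescaling and 0.72 with the mean sum.

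On chromosome 17, from 37609739 to 39567559 (GENCODE 29, GRCh38, 17q12), 20 of 22 tested genes were lower in HCC827_Er (median log2 difference -2.66, SD over genes 1.26), among them all 16 protein-coding genes, from DDX52 to LASP1 and LASP1NB, but GPR179; RPL23 fell from 19025 to 2995 FPKM, PSMB3 from 2308 to 295 FPKM. In the test of shared reads the median without RPL23 was -2.65, so the fall of the other genes did not rest on that gene. With 20 of 22 genes lower, leaving out 1 gene could hardly move the median. Whether reads shared with pseudogenes lowered RPL23 itself was not tested. A bias of transcript length or GC content is argued against by a median of 0.54 among genes of the same length and GC on other chromosomes. One change shared by the whole segment, such as a gain in HCC827 or a loss in HCC827_Er, is a candidate explanation that stays open, and copy number was not tested. The SD was 0.44 over the 15 lower protein-coding genes, and 12.7% of 10000 random sets of lower genes were spread as narrowly, but this compared genes selected as lower and decides nothing.

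On chromosome 14, 221 of 255 tested genes were higher in HCC827_Er, and on chromosome X 234 of 270, both 86.7%, against 51.5% over all chromosomes, 71.3% on chromosome 2, 34.6% on chromosome 12 and 25.3% on chromosome 13. Most chromosomes departed from the overall share, 17 of 23 at an adjusted p under 0.05. Of these, 9 (2, 3, 11, 12, 13, 14, 16, 19 and X) stood at a permutation p of 0.0001, the smallest the permutations can give, and an adjusted p of 0.000256. The permutations and the exact tests below treat neighbouring genes as independent, so their p-values may be too small. Genes of matched length and GC on other chromosomes were higher in at most 49.1%, which argues against a bias of length or GC. Leaving out any 20 Mb bin left at least 85.7%. With 221 of 255 and 234 of 270 genes higher, no bin left out alone could move the share far. Bins were not left out together, so whether a few local clusters are the whole cause is not decided. The table lists 41.6% of the protein-coding genes of chromosome 14 and 33.0% of those of X, against 25.6% of those on other chromosomes (Fisher's exact test, p = 2.52e-17 and 2.48e-06). A shift of each whole chromosome may account for both values, as a hypothesis found and tested on the same table, and a difference in chromosome number was not tested.

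Epithelial and lung lineage genes were higher, and VIM, ZEB1, AXL and FGFR1 lower, in the libraries labelled HCC827_Er. The lowest correlation within a label was 0.991 and the highest between labels 0.809, so no library resembled the other label over the listed genes. The labels already did not overlap for 96.1% of these genes, so a gap between the correlations was largely built in. It is thus only weak evidence against a single mislabelled library. The 5 tested neighbours of EGFR had a largest log2 difference of 0.94, or 1.19 (largest SE 0.19) with the mean sum. SEC61G was among the 3 most abundant of the listed genes in every library. These values argue against high expression of the tested neighbours in only 1 of the lines. They do not decide it for EGFR, which was not analysed here. An exchange of the labels of all libraries cannot be told apart from a difference of the lines, since the values are symmetric and 0 columns carry a name that differs from the sample titles. A difference of the lines themselves stays open and untested.

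The real grouping called 2345 genes with limma, 1 of 10 splits of the 6 libraries did so, and the highest of the other splits was 0, or 3 at an unadjusted p under 0.05; 10 splits are too few for a share under 0.05. Almost all listed genes already differed between these lines, so the other splits had little left to call.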
